A study of Homo sapiens with 12 samples.

How the data were processed

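Gene expression was measured in 12 samples of total RNA from SW480 ADH human colon carcinoma cells, cultured for 72 h per the labels' protocols and hybridised to Affymetrix microarrays, whose model is not given in the sources used here. The deposited values are log2 expression values per Ensembl gene ID and array, and RMA and affy are named in the submitters' processing notes, with no version, genome build or annotation release given in the sources used here. RMA in its usual form corrects the background, normalizes quantiles across arrays and summarises probes on the log2 scale. Such values are relative within an array, so a change of total RNA per cell leaves no trace in them, and large differences are compressed where a gene lies near the lower end of the scale. That the deposited values are on the log2 scale was read from the values, which lie between 3.91 and 14.12 with medians of 7.20 to 7.32 in the 12 arrays. No raw intensities were used here, so the signal over background of single genes was not analysed.

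Samples were assigned to Mock, SPRY2 WT, SPRY2 S112A and SPRY2 Y55F from their titles, which also number the replicates from 1 to 3. The labels state 3 independent experiments, each in triplicate, and do not say whether a number marks an experiment. The p-values therefore measure the spread between these arrays, which may be partly technical. The labels also do not say whether each construct was studied in 1 or several transfected cell populations. No pair of arrays held identical values.

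Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values of all 24916 gene IDs, with no filter. A model with 1 mean per group was fitted to all 12 arrays, so that the 4 groups shared the estimate of spread (8 residual degrees of freedom). Where 1 group varied more than the others, the shared estimate understates its spread, and the p-values of its comparisons can be too small. The 6 comparisons between groups were tested with eBayes, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. The moderated F test over the 4 groups was adjusted in the same way. A fold is 2 to the power of the difference of mean log2 values. Sharing between constructs was measured by overlap of calls per direction, by Pearson and Spearman correlation and by covariance across gene IDs. Its baseline came from 1000 simulated sets of unchanged groups for correlation and covariance, and from 100 separately drawn sets that were fitted to count calls. Both were built from the arrays' deviations from their group means in random order and with random signs. Random order breaks any link between same-numbered arrays, so a second simulation of the same size, added after seeing the data, shuffled the arrays within each number only. Another 100 sets in random order gave the overlap of the largest falls. These tests, the alternatives and the rule for named genes were fixed before the data were examined, apart from those named as later choices in the closing section.

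The procedure was tested on simulated data with 200 changed IDs among 24916, for the comparison of WT with Mock in 10 sets. It recovered 83.1% of 1.5-fold, 96.7% of 2-fold and 99.8% of 4-fold changes, and 5.67% of its calls were false. The simulated noise was independent between IDs and between arrays, and the deviations of the real arrays were in part correlated. These shares therefore do not carry over to the real lists.

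The replicate numbers were checked for pairing through the correlation of same-numbered arrays' deviations from their group means. For WT and Mock these were 0.14, 0.46 and 0.36, and for Y55F and S112A they were 0.61, 0.12 and 0.40, so that by the rule used here, a correlation above 0.1 in every pair, the numbers pair the samples of these 2 comparisons. The pairing comes from the data and not from the labels. In the other 4 comparisons at least 1 pair lay below 0.1. The comparisons were fitted without the block, as fixed beforehand, and fits with the block are among the alternatives.

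None of the 24916 gene IDs matched an Ensembl ID in the RefSeq gene table used here, whose Ensembl column held 0 entries, and the expression file does not pair IDs with names. Genes are therefore given by ID. The rule for named genes took, for each construct against Mock, the IDs with the largest rises and falls among those past the threshold whose 3 arrays all lay above or all below those of the other group. Without symbols this was shortened, after the IDs were seen to be unnamed, to the 2 largest rises and the 2 largest falls over the 3 comparisons with Mock, and the same 4 IDs were followed through all groups. The check of the introduced SPRY2, gene lists for signalling, epithelial, mesenchymal and other programmes, and markers of other cell types had been fixed beforehand and were not run, since each needs gene symbols.

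The alternatives were leaving out the third of IDs with the lowest mean, fitting only the groups compared, eBayes with trend and robust, centring arrays on their median, quantile normalizing again, the replicate number as a fixed or random block, array weights, adjustment over all 6 comparisons, a minimum change of 1.5-fold, Spearman correlation and leaving out each array in turn.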

Results

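RNA levels were measured on Affymetrix microarrays in SW480 ADH cells, an adherent subline of the SW480 human colon carcinoma line. Cells were either mock transfected or transfected with SPRY2, which encodes Sprouty2, an intracellular regulator of receptor tyrosine kinase signalling. SPRY2 was introduced as the wild type (WT), as the S112A mutant, in which a serine is replaced by alanine, or as the Y55F mutant, in which a tyrosine is replaced by phenylalanine. Each of the 4 groups held 3 arrays, 12 in all, and each array gave a log2 expression value for 24916 Ensembl gene IDs. The files and tables used here do not pair these IDs with gene symbols. The level of SPRY2 itself, other single genes by name and gene lists are therefore not analysed here, and the changes are described by their number, size, direction and sharing between groups, with 4 IDs as examples.

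The arrays were alike in their distribution and fell into their 4 groups. Array medians lay between 7.20 and 7.32 on the log2 scale. Correlations across gene IDs were 0.995 to 0.998 for the 12 pairs of arrays within a group and 0.985 to 0.994 for the 54 pairs between groups. The first principal component carried 39.4% of the variance and placed the WT arrays at one end, the S112A arrays at the other and the Mock and Y55F arrays between them. The second component carried 26.2% and set the Y55F arrays apart from the other groups. The root mean square SD between the arrays of a group was 0.11 in the WT and Mock groups, 0.12 in the Y55F group and 0.13 in the S112A group. Limma's moderated F test found 7292 of the 24916 gene IDs, 29.3%, to differ among the 4 groups. The number of arrays, 3 per group, limits the precision of each value.

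**Figure D1:**
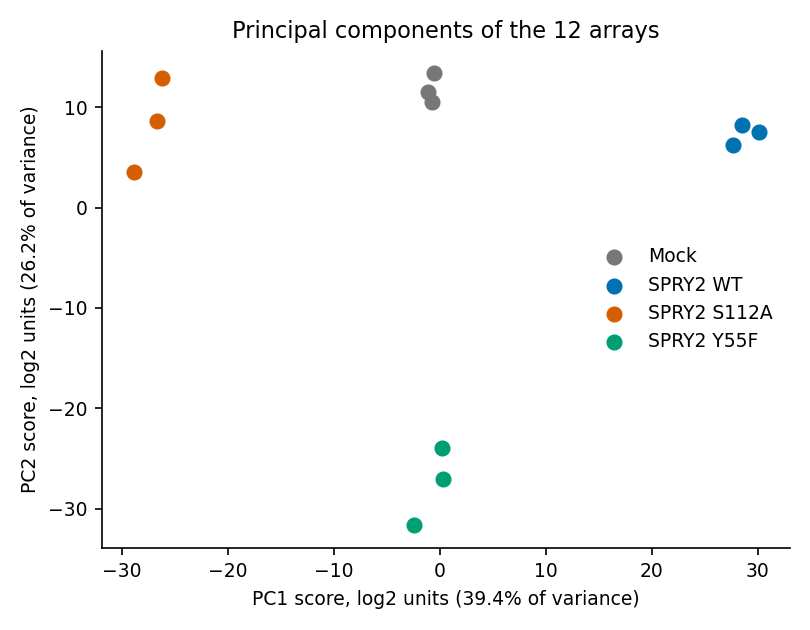
Scores of the 12 arrays on the first and second principal components of the log2 values, in log2 units, with 1 point per array and colours for the groups. The WT and S112A arrays lie at opposite ends of the first component (39.4% of the variance), and the Y55F arrays lie apart on the second (26.2%).

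The comparison of WT with Mock asked which genes changed when wild-type SPRY2 was introduced. In WT cells 1321 gene IDs rose and 1032 fell, 2353 in all or 9.44% of those tested. Large falls outnumbered large rises: 396 IDs fell and 315 rose by at least 1.5-fold, 146 fell and 88 rose by at least 2-fold, and 26 fell and 13 rose by at least 4-fold. The IDs that fell at least 2-fold had a median level of 9.08 in Mock and 7.35 in WT, while the median of all IDs was 7.27 in Mock. Those that rose at least 2-fold had a median of 7.54 in Mock and 8.96 in WT. The largest fall was that of ENSG00000147676, which stood at 12.85 ± 0.05 in Mock and 6.70 ± 0.94 in WT (log2, SD, n = 3), a 70.8-fold difference with adjusted p = 1.43e-07 in limma. The next was ENSG00000104413, at 10.92 ± 0.07 in Mock and 5.94 ± 0.20 in WT, a 31.6-fold difference with adjusted p = 2.00e-10 in limma. Both WT levels lie below the median of all IDs in WT cells, 7.28, and signal over background was not analysed, so that these and the later folds are ratios of deposited values and may understate the change. The largest rise was that of ENSG00000145824, from 7.22 ± 0.40 in Mock to 12.87 ± 0.06 in WT, which is 50.1-fold with adjusted p = 8.45e-10 in limma. ENSG00000207081 rose from 4.89 ± 0.18 to 9.25 ± 0.07, a difference of 4.36 in the deposited log2 values with adjusted p = 7.67e-07 in limma. Its Mock level lies near the low end of the Mock arrays, whose lowest values were 3.95 to 4.02, so no fold is given against it or against S112A cells. Over all 2353 changed IDs the median change was 1.35-fold and the smallest 1.11-fold. With array weights, 4230 IDs passed, and without WT replicate 3 the majority direction turned, with 931 higher and 947 lower.

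**Figure D2:**
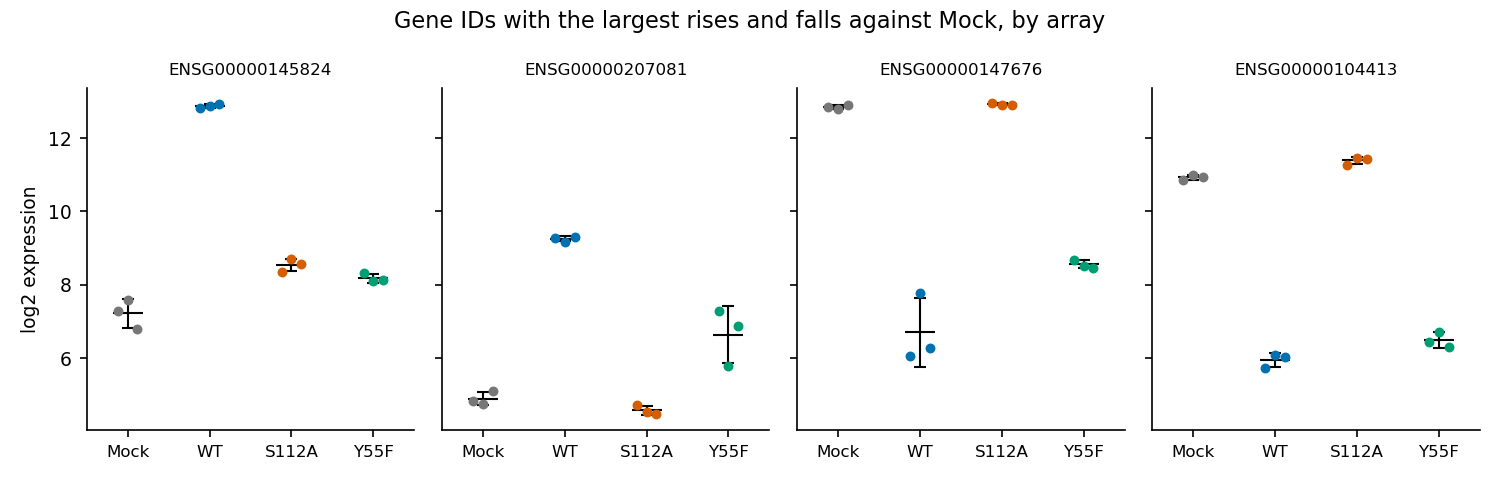
Log2 expression of the gene IDs with the largest rises (left pair) and the largest falls (right pair) over the 3 comparisons with Mock, with 1 point per array and bars for the group mean and SD (n = 3). Both IDs that fell in WT cells are also lower in Y55F cells than in Mock, at 8.56 and 6.49, and stand at 12.92 and 11.39 in S112A cells.

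In S112A cells, compared with Mock to see which genes changed with this mutant, 1465 gene IDs rose and 1773 fell, 3238 in all or 13.0%. By at least 1.5-fold 364 IDs were higher and 381 lower, with 97 higher and 87 lower by at least 2-fold, and 14 higher and 8 lower by at least 4-fold. The largest rise was 11.4-fold and the largest fall 9.90-fold, both smaller than the extremes in WT cells. The IDs that fell at least 2-fold had a median of 8.77 in Mock and 7.44 in S112A cells, and those that rose at least 2-fold went from 7.43 to 9.05. Neither of the 2 IDs with the largest falls in WT cells fell here. ENSG00000147676 stood at 12.92 ± 0.03 (log2, SD, n = 3), a difference from Mock of 0.07 with adjusted p = 0.953 in limma. ENSG00000104413 was higher than in Mock, at 11.39 ± 0.11, a difference of 0.46 ± 0.11 (SE) with adjusted p = 0.0167 in limma, and this call was lost without Mock replicate 1, S112A replicate 2 or S112A replicate 3, with differences of 0.43, 0.43 and 0.44. ENSG00000145824 rose 2.49-fold, from 7.22 to 8.54 ± 0.17, with adjusted p = 0.000153 in limma. ENSG00000207081 stood at 4.58 ± 0.12 against 4.89 in Mock, with adjusted p = 0.635 in limma. With array weights, 9119 IDs passed, 4648 higher and 4471 lower. With each array centred on its median, 1661 IDs were higher and 1460 lower, so that the majority direction turned.

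Y55F cells differed from Mock at 4019 gene IDs, 16.1% of those tested, with 2039 higher and 1980 lower, a near balance that turned without Mock replicate 1 (1487 higher, 1515 lower), Mock replicate 2 (1615 and 1689) or Y55F replicate 2 (1633 and 1690), and after quantile normalizing again (2137 and 2149). Large falls again outnumbered large rises, with 510 IDs lower and 391 higher by at least 1.5-fold, 192 lower and 76 higher by at least 2-fold, and 31 lower and 7 higher by at least 4-fold. The IDs that fell at least 2-fold had a median of 8.93 in Mock and 7.33 in Y55F cells, and those that rose at least 2-fold went from 7.82 to 9.44. The largest fall here was that of ENSG00000104413, which stood at 6.49 ± 0.21 (log2, SD, n = 3), 21.6-fold below Mock with adjusted p = 2.43e-09 in limma. It was followed by ENSG00000147676 at 8.56 ± 0.11, 19.6-fold below Mock with adjusted p = 2.69e-06 in limma. ENSG00000145824 rose 1.94-fold to 8.18 ± 0.12, with adjusted p = 0.00125 in limma. ENSG00000207081 rose by 1.75 in the deposited log2 values to 6.64 ± 0.78, with adjusted p = 0.000873 in limma. Its Y55F arrays varied more than those of the other groups, so this p may be too small. The largest rise was 14.5-fold. With each array centred on its median, 2652 IDs were higher and 1505 lower, a share of higher calls of 63.8% in place of 50.7%.

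**Figure D3:**
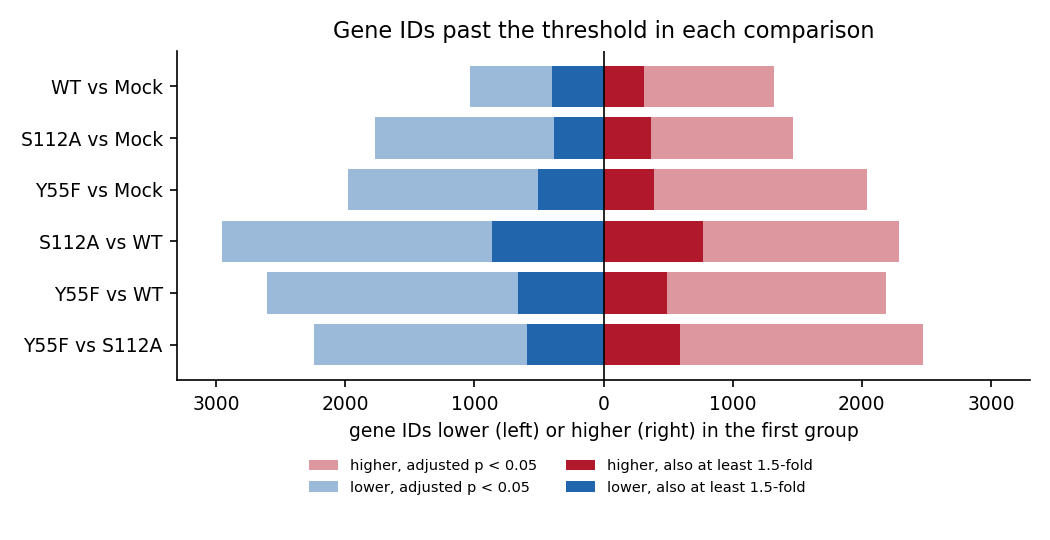
Number of gene IDs past limma's adjusted p of 0.05 in each of the 6 comparisons, with those higher in the first-named group to the right and those lower to the left. Pale bars count all such IDs and dark bars those that also changed at least 1.5-fold, and the S112A to WT comparison has the longest pale bar to the left (2953) and the Y55F to S112A comparison the longest to the right (2472).

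The direct comparisons between constructs asked whether the mutants differed from the wild type and from each other. In the fits to all 12 arrays, each called more gene IDs than any comparison with Mock, except with array weights, where S112A and Mock gave 9119 IDs, Y55F and Mock 5749, S112A and WT 8265, Y55F and WT 5277 and Y55F and S112A 6829. S112A and WT cells were farthest apart, with 5243 IDs past the test, of which 2290 were higher and 2953 lower in S112A cells. At least a 1.5-fold difference was seen for 767 of the higher and 867 of the lower IDs. The root mean square log2 difference over all IDs was 0.35 between S112A and WT, 0.25 between WT and Mock, 0.24 between S112A and Mock and 0.27 between Y55F and Mock, where the spread between arrays alone would give 0.10. Of the 5243 IDs, 592 had changed in opposite directions against Mock, 1869 had passed against Mock in S112A cells alone, 1134 in WT cells alone, 153 in both with the same direction and 1495 in neither. ENSG00000147676 was 74.4-fold higher in S112A than in WT cells, with adjusted p = 5.30e-08 in limma, and ENSG00000104413 was 43.6-fold higher, with adjusted p = 3.15e-11 in limma. ENSG00000207081 was lower, with a log2 difference of -4.67 and adjusted p = 1.60e-07 in limma, and ENSG00000145824 was 20.1-fold lower, with adjusted p = 2.96e-09 in limma. With each array centred on its median, 2622 IDs were higher and 2447 lower in S112A cells, which turned the majority direction.

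Y55F and WT cells differed at 4793 gene IDs or 19.2%, of which 2190 were higher and 2603 lower in Y55F cells. By at least 1.5-fold, 491 were higher and 662 lower. ENSG00000145824 was 25.9-fold lower in Y55F than in WT cells, with adjusted p = 3.40e-09 in limma, and ENSG00000207081 was 6.10-fold lower, with adjusted p = 3.63e-05 in limma. The falls of the other 2 IDs were less deep in Y55F cells, 3.61-fold above the WT level for ENSG00000147676 with adjusted p = 0.00146 in limma, and 1.47-fold above it for ENSG00000104413 with adjusted p = 0.00413 in limma. For ENSG00000147676 the WT arrays (SD 0.94) varied more than those of the other groups. The same held for the Y55F arrays of ENSG00000207081 (SD 0.78), so the p-values of these 2 IDs may be too small. With each array centred on its median, 2948 IDs were higher and 1916 lower, a share of higher calls of 60.6% in place of 45.7%, and without WT replicate 3 the majority also turned, with 2058 higher and 1944 lower. Y55F and S112A cells differed at 4716 IDs or 18.9%, with 2472 higher and 2244 lower in Y55F cells, and 592 each way by at least 1.5-fold. ENSG00000104413 was 29.7-fold lower in Y55F than in S112A cells, with adjusted p = 2.55e-10 in limma, and ENSG00000147676 was 20.6-fold lower, with adjusted p = 1.91e-06 in limma. ENSG00000207081 was higher, with a log2 difference of 2.06 and adjusted p = 0.000201 in limma. ENSG00000145824 did not differ past the threshold, with a log2 difference of -0.36 and adjusted p = 0.156 in limma.

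The changes against Mock were shared between constructs to different degrees. Of the 24916 gene IDs, 6400 changed in at least 1 construct, 3778 of them in 1, 2034 in 2 and 588 in all 3. WT and Y55F cells shared 968 changes of the same direction and 289 of opposite direction, so that 23.0% of the IDs called in both were opposite. S112A and Y55F cells shared 1183 of the same and 356 of opposite direction, 23.1% opposite. WT and S112A cells shared 410 of the same direction and 592 of opposite direction, 59.1% opposite. Lists drawn independently would share 190.1, 260.8 and 151.1 IDs of the same direction for these pairs, in that order, and 189.4, 261.5 and 154.7 of opposite direction. In 100 sets of unchanged groups simulated against shared controls, no more than 1, 24 and 1 IDs were called in both with the same direction, and 0 with opposite directions. With no change simulated, few IDs can pass in either comparison. These counts therefore do not measure what shared controls add to the overlap of the longer real lists. Among IDs that also changed at least 1.5-fold, a restriction chosen after seeing the data, 17.2% of the shared calls were opposite for WT and Y55F, 12.9% for S112A and Y55F and 60.6% for WT and S112A. Against Mock, 146 IDs were lower and 91 higher in all 3 constructs, where independent lists would share 5.84 and 6.36. The IDs that rose in WT and fell in S112A cells numbered 350, of which 107 fell, 82 rose and 161 did not pass in Y55F cells. Independent lists would give 7.47, 7.69 and 78.8. The 242 that fell in WT and rose in S112A cells held 89 that fell, 52 that rose and 101 that did not pass in Y55F cells, against 4.82, 4.97 and 50.9. The remaining mixed patterns over all 3 constructs held 12 IDs (higher in Y55F cells only) and 9 (lower in Y55F cells only), against 6.01 and 6.17. An excess over independent lists was thus not limited to IDs that changed the same way in all 3 constructs. Such lists treat all IDs as equally likely to pass. The third of IDs with the lowest mean held few calls: 84 higher and 27 lower of 2353 in WT cells. In S112A cells it held 107 higher and 52 lower of 3238, and in Y55F cells 66 and 82 of 4019. Unequal chances to pass raise every one of these patterns, so the excess by itself does not measure sharing.

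Across gene IDs, which are not independent replicates, the log2 changes against Mock of WT and Y55F cells correlated at r = 0.34, with a Spearman rho of 0.22, and those of S112A and Y55F cells at r = 0.33, with a rho of 0.33. For WT and S112A cells r was -0.08 and rho 0.04, so that the sign depended on the measure. Simulated unchanged groups that share their controls gave a mean r of 0.48, 0.49 and 0.48 for these pairs. Those groups hold spread alone, while the real changes were larger, with a root mean square of 0.24 to 0.27 against 0.10 from spread. The simulated r is therefore no baseline for the real groups, and the correlations by themselves do not decide on sharing. The covariance was 0.0220 for WT and Y55F, 0.0207 for S112A and Y55F and -0.00474 for WT and S112A, against simulated means of 0.00461, 0.00470 and 0.00467. The differences, 0.0174, 0.0160 and -0.00940, estimate the covariance without the part that the shared controls add. With same-numbered arrays kept together in the simulation, an addition made after seeing the data, they were 0.0181, 0.0167 and -0.00864. With 3 Mock arrays the controls could not be split into parts of at least 2 arrays, and part of the overlaps may come from the shared controls.

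**Figure D4:**
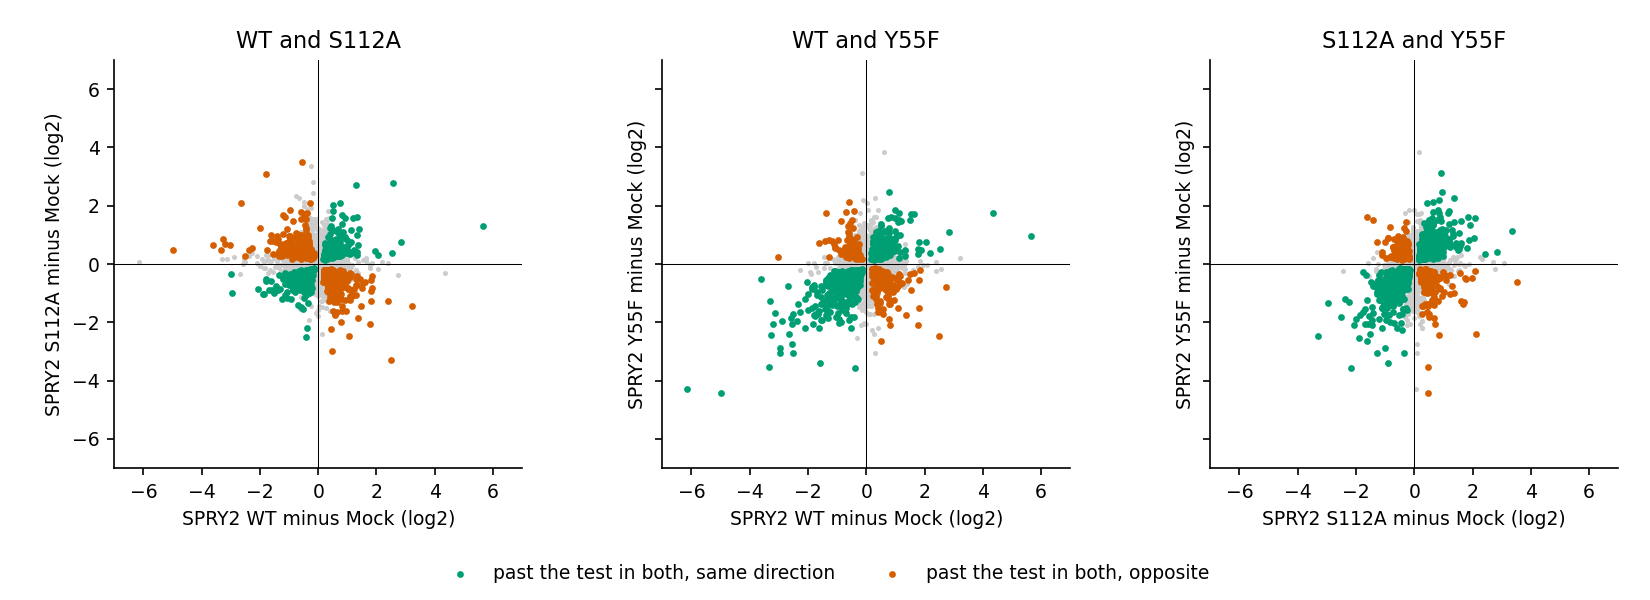
Log2 change against Mock in 1 construct plotted against that in another, for the 3 pairs of constructs, with 1 point per gene ID. Green points passed limma's threshold in both with the same direction (410, 968 and 1183 from left to right), orange points passed in both with opposite directions (592, 289 and 356), and grey points did not pass in both.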

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

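Of 344 values under alternatives, 330 kept their direction and their side of the threshold, or stayed within 1.5 times a count. Some of these could not move, since centring and the fixed block leave the correlations unchanged by construction. Counts whose majority direction turned are among those kept. The first within-group axis as a covariate, the correlations after quantile normalizing again, the overlaps at 1.5-fold and the simulation with numbers kept were chosen after seeing the data. Requiring a change of at least 1.5-fold, which by construction can only lower a count, left 711 IDs for WT and Mock, 745 for S112A and Mock, 901 for Y55F and Mock, 1634 for S112A and WT, 1153 for Y55F and WT and 1184 for Y55F and S112A. Array weights raised the counts to 4230 for WT and Mock, 9119 for S112A and Mock, 8265 for S112A and WT and 11786 for the F test, and the cause was not tested. They gave Mock replicate 1 a weight of 5.31 and S112A replicate 2 a weight of 6.06, against 0.467 to 1.35 for the other arrays. The correlation of WT and S112A changes turned from -0.0818 to 0.0397 with Spearman ranks, and the cause was not tested. Leaving out 1 array gave 1788 to 2035 IDs for WT and Mock, 2467 to 2990 for S112A and Mock, 3002 to 3885 for Y55F and Mock, 4351 to 4874 for S112A and WT, 3755 to 4688 for Y55F and WT, 3747 to 4762 for Y55F and S112A and 6420 to 7454 for the F test. The replicate block as a fixed term gave 2662, 3630, 4580, 5804, 5396 and 5288 IDs for these 6 comparisons, all within 1.5 times the counts without it, and changed no call of the 4 IDs against Mock. As a random block, with a correlation of 0.118, it gave 2662 for WT and Mock. As a hint from the data and not the design, 11 of the 12 arrays correlated best, among arrays of other groups, with one of their own number, while the lowest correlation of same-numbered arrays was -0.29 (Mock and S112A, replicate 3). The share of opposite calls was 52.2% (array weights) to 60.4% for WT and S112A, 19.9% to 27.3% for WT and Y55F and 19.9% to 26.6% for S112A and Y55F over 20 alternatives, the 1.5-fold minimum not among them, and 60.6%, 17.2% and 12.9% with it. The axis as a covariate gave 3283, 4397, 5434, 6631, 6293 and 6117 IDs and 9261 in the F test; it was taken from the residuals, which lowers the spread by construction. Among the alternatives run for single IDs, which leave out the 1.5-fold minimum and the adjustment over 6 comparisons, the calls of the 4 IDs against Mock held except that of ENSG00000104413 in S112A cells, lost without Mock replicate 1, S112A replicate 2 or S112A replicate 3. The alternatives on probe sets per gene were not run, since the file has 1 row per ID, nor were those on SPRY2 and the gene lists. Without raw intensities, what signal over background limits is open.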

Other observations

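The lists of largest falls and rises and the tests of the shared Mock arrays, of high Mock arrays, of the replicate number and of other splits of the arrays were chosen after the results were seen. The 50 largest falls in Y55F cells (median -2.07 on the log2 scale) held 33 IDs called lower and 7 higher in WT cells, and 28 called lower and 8 higher in S112A cells. The 50 largest falls in S112A cells held 26 IDs called higher and 9 called lower in WT cells, with a median change of +0.42 there, and 37 called lower and 3 higher in Y55F cells. Those of WT cells held 41 called lower and 2 higher in Y55F cells, and 8 called lower and 15 higher in S112A cells. The 50 largest rises of WT cells held 14 IDs called higher in S112A cells and 15 in Y55F cells, and 20 and 11 called lower. Those of S112A cells held 11 called higher and 13 lower in WT cells, and 18 higher and 10 lower in Y55F cells. Those of Y55F cells held 30 called higher and 5 lower in S112A cells, and 16 higher and 9 lower in WT cells. All these comparisons share the 3 Mock arrays, and no value for unchanged groups was computed for these counts.

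WT and S112A cells changed 592 gene IDs in opposite directions, 59.1% of those called in both, where independent lists would give 50.6% and the pairs with Y55F gave 23.0% and 23.1%. Among IDs also changed at least 1.5-fold, 114 were opposite and 74 in the same direction. The opposite overlap was at least 3.66 times that of independent lists after centring or quantile normalizing again. Without either step it was 3.83 times. This argues only against shifts of whole arrays or differences in their overall distribution, left in the deposited values, as the whole cause. The original normalization was not varied, so its effect on single IDs stays open. Among the 16611 IDs left without those of lowest mean, the ratio was 2.65. The IDs left out held few calls, 84 higher and 27 lower of 2353 in WT cells. In S112A cells they held 107 higher and 52 lower of 3238. They can therefore hold only a part of the 592. The ratio without them was thus largely set in advance, and decides nothing further on dim genes. Shared Mock arrays raise the covariance on average, and it was -0.00474. This lay below the central 95% of simulated values, -0.000928 to 0.0140, and -0.00104 to 0.0106 with same-numbered arrays kept together. On ranks, however, the changes of WT and S112A cells were weakly positively related (Spearman rho 0.04), so the sign depends on the measure. The same-direction overlap also exceeded independence, at 2.71 times, and the share of opposite calls was 52.2% with array weights. It stays open, as a hypothesis not tested here, whether the wild type and the S112A mutant may act on a common set of genes in opposite ways, or whether separately transfected populations differed.

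WT and Y55F cells shared 18 of their 50 largest falls, S112A and Y55F cells 16, and WT and S112A cells 0. Independent lists would share fewer than 1, but simulated unchanged groups with shared controls shared 15.1 on average and up to 39, so the number by itself decides nothing. The simulated lists hold smaller falls, with a 50th of -0.40 on average and the largest in any draw at -2.07 on the log2 scale, where the real 50th was -1.63 in WT and -1.73 in Y55F cells and the 18 IDs had medians of -2.62 and -2.29, sizes that the choice of the largest falls in part sets. Mock values high by chance or otherwise would lower the same IDs in S112A cells too, where their median change was +0.17, a ratio of -0.064 to the WT change. This argues against the Mock arrays as the source of these falls. Leaving out 1 array left at least 18 shared. That cannot decide on 1 deviating array, since simulated unchanged groups already shared 15.1 on average. Of the 18 IDs shared with all arrays included, 3 were called lower and 5 higher in S112A cells. The 16 falls shared by S112A and Y55F cells showed the converse, with median changes of -1.66 and -2.08 there and +0.14 in WT cells. An effect of the constructs and differences between separately transfected populations both stay open.

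The first axis of spread held 37.7% of the variance within groups, where 8 equal axes would hold 12.5% each, the least a first axis can hold, and unrelated arrays were not simulated. Quantile normalizing again lowered its share by 0.711%, to 37.5%, which argues against differences in the overall distribution of values as its whole source. Array scores on the axis nevertheless went with the deviation of the array median (12 arrays, r = 0.78, exact permutation p = 0.00540, rho = 0.80, exact permutation p = 0.00463, and r = 0.77 without the 2 arrays farthest from the median) and with that of the interquartile range (r = -0.78, exact permutation p = 0.00154, rho = -0.90, exact permutation p = 0.00231, and r = -0.82 without the 2 farthest). Over these 2 relations the adjusted p of r was 0.00540 and 0.00309 (Benjamini-Hochberg, exact permutation). The replicate number explained 47.3% of the scores' spread (exact permutation p = 0.157 over 216 relabelings). The mean correlation of same-numbered arrays, over all gene IDs, was 0.19 (exact permutation p = 0.0185, one-sided), which goes with a shared experiment behind each number, while replicate 3 of Mock and of S112A correlated at -0.29, and whether the number accounts for this axis stays open. No biological explanation was tested for this pattern.

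For each comparison between 2 groups, the 10 splits of the 6 arrays are too few for a share under 0.05. The real split was the only 1 to call as many IDs, at 2353, 3238, 4019, 5243, 4793 and 4716, and the highest of the other splits called 0 in each. Where the numbers pair the samples, for WT and Mock and for Y55F and S112A, these include the 3 other splits that part all 3 pairs, while the remaining 6 part 1 pair. For the F test, the real grouping called 7292 IDs and the highest of the other splits 755. Of 100 drawn splits, 1, the real one, was as large, which is the smallest share that 100 draws can give. This argues against a random assignment of interchangeable arrays as the source of the count. The splits ignore any link between same-numbered arrays and do not cover chance differences between transfected populations.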
